A study of Homo sapiens with 8 samples.

How the data were processed

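RNA immunoprecipitation sequencing was analysed for 8 samples of HepG2 cells that expressed Cas9 and 3 x Flag-QKI7: input and Flag IP RNA, with a control guide (sgNS) or a guide against METTL1 (sgMETTL1), and 2 replicates of each. Per the labels' protocols, cells were cross-linked with UV and sonicated, ribosomal RNA was depleted, and stranded libraries were sequenced on an Illumina NovaSeq. Samples were grouped by their titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

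Per the submitters' processing notes, the build was GRCh38 and STAR was used; its version, the peak caller, its input normalisation and its threshold are not given in the sources used here. The authors deposited 1 peak list per pair of IP and input samples, per the sample descriptions, with replicates not pooled, and the lists differed between replicates. Each row holds a gene name, strand, exon blocks and 3 measurements. The fold enrichment of a peak is a ratio, as deposited by the authors, of IP over input, with no stated scaling between lists. The p-value of each peak, and the base-10 logarithms of p and of the FDR, which exceed any usual range and were therefore handled as a score, are as deposited by the authors. A p-value of 0 was listed for 621, 565, 270 and 288 peaks, so ranks by p used the logarithm. The largest listed FDR was about 5% in every list. No read counts were used here, so the depth behind a value is known only as far as the model below implies it.

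The fold and p of a peak belong to that peak and list. Some folds, the strongest fold of 14.1 to 14.9% of genes of all 4 lists, were whole multiples, within rounding, of a step fitted to each list (2.315 and 2.113 with sgNS, 3.05 and 2.778 with sgMETTL1), against 1.61 to 2.41% for a step 7% larger. A binomial model took the step as the input over the IP read total, with 1 input read at whole steps. It gave the listed p within 1.5% for 69.5 to 76.4% of peaks of at most 130 bases at 4 to 30 steps. The step had been fitted to folds and p of the same lists. In that model folds are already scaled by read totals, and the step sets how coarse they are. The steps therefore do not show that the lists differ in scale, and no source states the scale. Since no scaling between lists is stated, folds were used to rank peaks within a list. The planned comparison of log2 folds between lists was kept as an alternative. That planned comparison was run first, and ranks were chosen after its results had been seen. The comparison on ranks took the strongest fold of each of the 4150 genes of all 4 lists, converted it to a rank within the list and then to a normal score, and compared 2 sgMETTL1 with 2 sgNS lists with limma 3.58.1 in R 4.3.3 (Benjamini-Hochberg FDR of 5%, two-sided). Camera with a preset correlation of 0.01, an estimated correlation, and fry were run on gene lists with at least 3 members there. The tests planned for read counts did not apply to peak lists and were not run.

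Overlap was counted over exon blocks on the same strand, at least 1 bp, with exact Clopper-Pearson intervals at 95% (scipy 1.17.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6; figures with matplotlib 3.10.9). A gene was lost when both sgNS lists and neither sgMETTL1 list named it, and gained in the reverse case. Gene lists were tested with Fisher's exact test against the genes with a peak in any list. Coordinates are 1-based, and a gene's position is that of its strongest peak in the first list that holds it. Names were matched to RefSeq genes of GRCh38.p14: 6206 of 6520 were current symbols, 303 matched through 1 older symbol and 11 did not match, and 99.7% of the 42083 peaks lay in the span of their gene. Between 62 and 102 peaks per list stood at the same place under another gene's name and are uncertain between them. Transcript parts (UTR, coding, intron) and motifs were not analysed here, since no genome sequence or transcript models were used; the position within the gene's span was used in their place.

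The groups, the 20 gene lists, the overlap rule, the alternatives and the rule for named genes were fixed in advance, except for the ranks, the ranking of peaks by fold, the background of all protein-coding genes and the position within the gene's span, which were chosen after the data were seen. That rule takes the 12 genes with the best mean within-list rank of the fold among genes in both lists of a guide, the 12 lost and 12 gained genes with the best ranks, METTL1, WDR4 and QKI, and up to 4 members per gene list with the best rank. The alternatives were 50% reciprocal overlap, peak overlap in place of names, equal numbers of top-ranked peaks, a fold of at least 2 times the list's minimum, the mean of a gene's peaks, log2 folds, the replicate number as a block, another background, and leaving out each list in turn. The overlap count and limma's fit were tested on simulated data: the overlap count returned 300 and 200 of 500 simulated peaks as made, and limma on the 4150 genes made 2 false calls and recovered 70% of genes changed by a score of -3, 36% at -2 and 4% at -1.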

Results

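The series measured which RNAs came down with the RNA-binding protein QKI7, an isoform of Quaking, in HepG2 cells, a human liver cancer line that here also carried Cas9 and a Flag-tagged QKI7 transgene. Cells received a control guide (sgNS) or a guide against METTL1 (sgMETTL1), the enzyme that with WDR4 places 7-methylguanosine on RNA, and RNA was recovered with a Flag antibody after UV cross-linking. The 8 samples formed 4 groups of 2: input and immunoprecipitated (IP) RNA for each guide. The data analysed were 4 lists of peaks, 1 for each pair of an IP and an input sample, so that each guide had 2 lists. The fold enrichment and p-value of a peak are the authors' own values for that peak, and the number of reads behind them is not listed.

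The first question was which transcripts QKI7 was found on and how repeatably. The lists held 11562 and 11038 peaks in 5570 and 5359 genes with sgNS, and 10095 and 9388 peaks in 5091 and 4981 genes with sgMETTL1. Together they named 6520 genes, of which 6485 are protein-coding, and 4150 of them (63.7%) were in all 4 lists. In replicate 1 of sgNS, 78.8% of peaks shared at least 1 base on the same strand with a peak of replicate 2 (95% exact binomial interval 78.1 to 79.6), and 83.5% in the other direction (82.8 to 84.2). With sgMETTL1 these shares were 73.4% (72.5 to 74.2) and 77.9% (77.0 to 78.7). Peaks of sgMETTL1 were met by an sgNS list for 82.6 to 85.3% of peaks, more often than by the other sgMETTL1 list, whereas peaks of sgNS were met by an sgMETTL1 list for 64.1 to 69.8%. With 50% reciprocal overlap this order turned for replicate 2 of sgMETTL1, whose peaks were met by the other sgMETTL1 list for 61.7% and by the sgNS lists for 59.2 and 60.3%. The centre of a peak lay in the last 10% of its gene's span, towards the 3' end, for 74.7 and 74.8% of peaks with sgNS and for 73.7 and 73.6% with sgMETTL1. The share of exon bases in that part was not computed, so these values do not show a preference of QKI7 for the 3' end. The intervals cover counting error only, and with 2 lists against 2 an exact test between the guides cannot go below p = 0.33.

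IGF2, which encodes a fetal growth factor, held the strongest peak by the authors' fold in 3 of the 4 lists. In replicate 2 of sgNS MEIOC stood higher. The IGF2 peak on the minus strand of chromosome 11 (GRCh38, 2129112 to 2147687, 4546 bases in exon blocks in replicate 1 of sgNS) was listed at 744-fold and 815-fold with sgNS and at 719-fold and 768-fold with sgMETTL1. ERO1A, an oxidase of disulfide formation in the endoplasmic reticulum, was listed at 663-fold and 485-fold with sgNS and 571-fold and 442-fold with sgMETTL1 (chromosome 14, 52639945 to 52643359). DVL3, a scaffold of Wnt signalling, was listed at 383-fold and 323-fold with sgNS and 360-fold and 250-fold with sgMETTL1 over a peak that joined 10 exon blocks in both sgNS lists (chromosome 3, 184165153 to 184173526). The kinase gene HIPK2, the activin receptor gene ACVR2A, RIPPLY3, MEIOC and SULT1C4 were also among the 12 best-ranked genes of both guides. SESN3, F2RL2 and ZNF43 were among the 12 only with sgNS, and TTF2, GNA13 and TNFSF15 only with sgMETTL1. Replicates differed widely at some of these genes, and MEIOC stood at 179-fold and 902-fold in the 2 sgNS lists.

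QKI itself had peaks in all 4 lists, whereas METTL1 and WDR4 had none in any, so the lists give no check of the knockout. Among equal numbers of top-ranked peaks by p (9388 per list), a QKI peak of 8 exon blocks on chromosome 6 (163415152 to 163571106) ranked 13th and 12th with sgNS and 44th and 52nd with sgMETTL1. The authors' fold for it was 10.1 and 9.94 with sgNS and 5.57 and 4.92 with sgMETTL1. The main peak nearer the 3' end (163572634 to 163574701 in replicate 1 of sgNS) ranked 328th and 313th with sgNS and 300th and 340th with sgMETTL1, with folds of 78.0 and 68.0 against 109 and 107. The peak of 8 blocks thus differed in rank by more than the replicates of either guide did, and the 3' peak did not. The difference between the guides was not tested for these peaks.

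**Figure D1:**
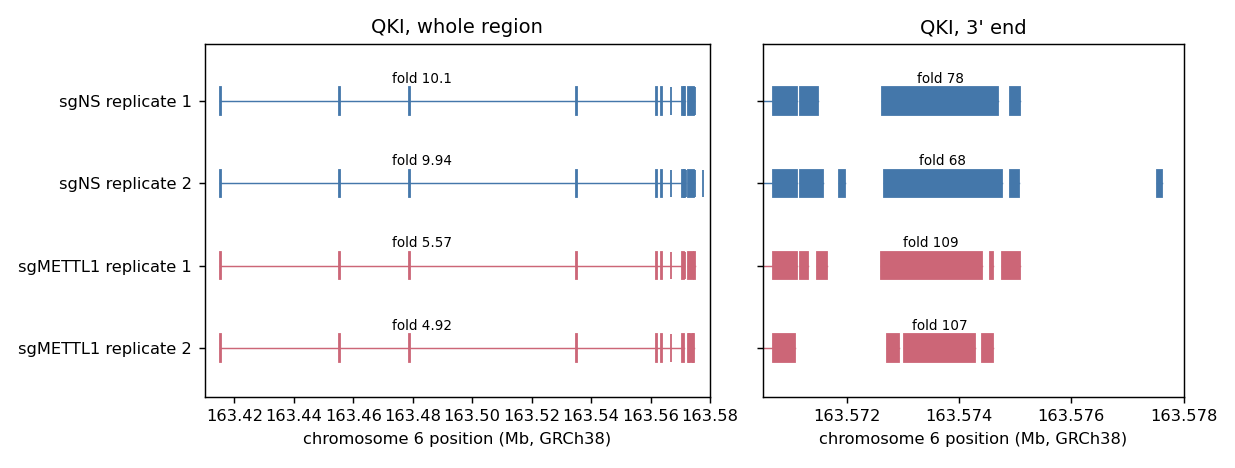
Peaks on QKI in the 4 lists, by position on chromosome 6 (Mb, GRCh38), for the whole region and its 3' end. Boxes are exon blocks, thin lines join the blocks of 1 peak, and the authors' fold is written above the peak of 8 blocks (10.1 and 9.94 with sgNS, 5.57 and 4.92 with sgMETTL1) and the main 3' peak (78.0 and 68.0, 109 and 107).

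Of the 20 gene lists fixed in advance, chromatin regulators were listed most completely with sgNS: 28 of 32 members had a peak in both sgNS lists and 24 of 32 (75%) in both sgMETTL1 lists. Examples are KMT2C, a histone H3 methyltransferase (authors' fold 70.3 and 67.4 with sgNS), and ARID2, a subunit of a SWI/SNF remodeller (55.3 and 54.4). HECT and RING ubiquitin ligases had 19 and 18 of 24 members, the same share as chromatin regulators with sgMETTL1, among them ZNRF3 (200-fold and 146-fold with sgNS) and RNF111 (44.8-fold and 57.6-fold). Of 11 known QKI target mRNAs, 8 were in both lists of both guides, with CTNNB1, which encodes beta-catenin, at 29.9-fold and 30.5-fold, FOXO1 at 38.1-fold and 40.3-fold and CDKN1B at 26.1-fold and 22.8-fold in the sgNS lists. Stress granule components had 15 of 25 members in both lists of either guide, and the Hippo pathway 16 of 31, with SAV1 at 34.7-fold and 30.7-fold.

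The remaining lists are given for sgNS and then sgMETTL1. G2/M genes had 12 and 10 of 23, MAPK and PI3K signalling 15 and 14 of 33, translation factors 11 and 9 of 24, ATF4 targets and the integrated stress response 12 and 13 of 24, p53 targets 9 and 9 of 22, and cholesterol biosynthesis 7 and 6 of 23. Glycolysis had 3 and 3 of 19, hepatocyte secreted proteins 5 and 5 of 34, interferon-stimulated genes 3 and 4 of 22, and fibroblast and blood cell markers 1 and 1 of 18, the 1 being LYZ. Cytosolic ribosomal proteins had 4 and 3 of 78 and replication-dependent histones 0 of 29 with either guide. The mitochondrial and the non-coding RNA lists could not be judged, since no peak lay on the mitochondrial genome and nearly all listed genes were protein-coding.

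Against genes with a peak in any list, Fisher's exact test (two-sided, Benjamini-Hochberg over the lists) called only chromatin regulators, in both sgNS lists (28 of 28 members with any peak, 76.3% of background genes, adjusted p = 0.0187), and not in both sgMETTL1 lists (24 of 28, adjusted p = 0.256). The difference between the guides was not tested. Against genes found in both replicates of either guide the call could not have been kept. There 95.2% of background genes were in both sgNS lists, and even 28 of 28 members gave an unadjusted p of 0.644 by Fisher's exact test. Against all protein-coding genes, a background chosen after the data were seen that does not control for expression, 11 lists were called with sgNS, among them chromatin regulators (adjusted p = 2.06e-12), ubiquitin ligases (2.86e-07), known QKI targets (0.00326), and, listed less often than the 24.7% of the background, ribosomal proteins (5.03e-05) and histones (0.00132).

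**Figure D2:**
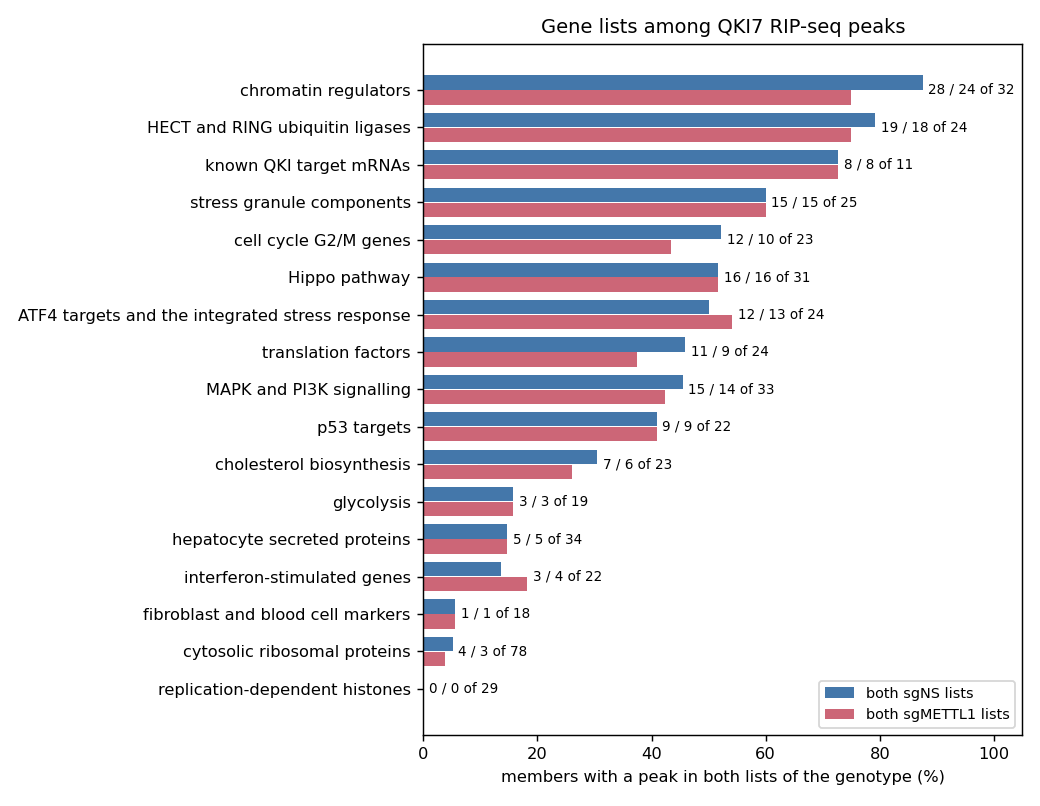
Percent of the members of each gene list with a peak in both sgNS lists (blue) or both sgMETTL1 lists (red), with the numbers beside the bars. Chromatin regulators stand highest with sgNS, at 28 of 32, and level with ubiquitin ligases with sgMETTL1 (24 of 32 and 18 of 24), and histones stand at 0 of 29.

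The central question of the series was whether loss of METTL1 alters the binding of QKI7 to transcripts. By presence of a peak, 302 genes were in both sgNS lists and neither sgMETTL1 list (lost), and 99 were in both sgMETTL1 lists and neither sgNS list (gained). The lost genes with the best ranks were MTFMT, which encodes the mitochondrial methionyl-tRNA formyltransferase (64.8-fold and 61.3-fold), the homeobox gene MKX (48.6-fold and 29.6-fold), ZDBF2 (30.1-fold and 38.0-fold), the adaptor gene NCK1 (37.0-fold and 29.6-fold), SRSF12, GLUD2, RASSF6, CXCL5, ZBTB14, PELI2, MYT1 and CENPK. The gained genes with the best ranks were the interferon-induced IFIT2 (27.4-fold and 41.6-fold with sgMETTL1), DLEC1 (33.5-fold and 27.8-fold), BICD1 (24.4-fold and 33.3-fold), TAC4, SYT13, CHST11, TMEM107, APC2, SIRPA, PCDHB14, GP1BA and C8orf31, now named LY6S-AS1. The folds of 12 of these 12 lost genes and 8 of these 12 gained genes were whole multiples of the list's step in both lists, against 0 and 0 for a step 7% larger. For MTFMT they were 28 and 29 steps, for MKX 21 and 14, for DLEC1 11 and 10 and for BICD1 8 and 12. These genes had been picked by their folds, and the share was far smaller over all lost or gained genes. A strongest fold at whole steps was held by 17.9 and 20.9% of all lost genes in the sgNS lists. For all gained genes it was 21.2 and 20.2% in the sgMETTL1 lists, against 14.1 to 14.9% of genes of all 4 lists. Such folds are coarse values, and the evidence beside them was small, with a -log10 p of 13.3 and 13.0 for MTFMT and 4.03 and 5.95 for BICD1. Most lost and gained genes were weakly supported: their median rank by p within their own lists was at the 82.9th and 85.5th percentile, where 100 is the weakest.

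No gene list was over-represented among lost or gained genes by Fisher's exact test. The smallest adjusted p among lost genes was 0.333, for ribosomal proteins (RPL22 and RPL37 of the 5 with any peak), and among gained genes 0.315, for the integrated stress response (ATF4 and PPP1R15A of 14). Other members of the lists among lost genes were the translation factor genes EIF2S1 and EIF4B, ERBB3, MAP3K2, ASXL1, DDIT4 and MSMO1, and among gained genes BRAF and IFIT2.

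The other splits of the 4 lists into 2 and 2 put 149 and 137 genes on one side only, against 401 for the split by guide, but only 3 splits exist. The excess of lost over gained genes changed with the number of peaks used and with how they were ranked. Among equal numbers of top-ranked peaks by p it was 200 against 153 at 9388 peaks per list and 127 against 127 at 4694, and of those lost genes 176 and 7 were among the 302. Ranked by fold it was 205 against 156 at 9388 peaks per list and 178 against 98 at 4694, with 200 and 64 of the lost genes among the 302.

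**Figure D3:**
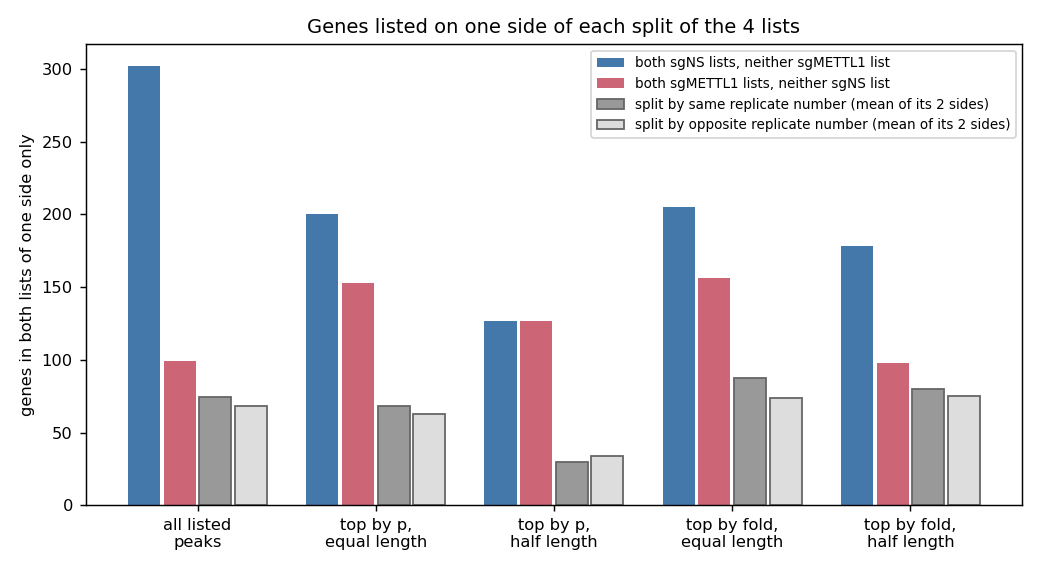
Number of genes in both lists of one side and neither of the other, for all listed peaks and for equal numbers of top-ranked peaks (9388 or 4694 per list), by guide (blue lost, red gained) and as the mean of both sides for the other splits (grey). With all peaks 302 were lost and 99 gained, and at 4694 peaks by p 127 and 127.

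The strength of binding was compared at the 4150 genes of all 4 lists, by the rank of each gene's strongest fold within its list. Peaks were not matched by position, so a gene's value can come from different sites in different lists. It also leaves out the gene's other peaks. For QKI the score difference was 0.209, from the 3' peak. Its peak over several exon blocks went from folds of 10.1 and 9.94 with sgNS to 5.57 and 4.92 with sgMETTL1. The comparison planned before the data were examined used the log2 of the authors' folds. It was run first. Ranks were put in its place after its results had been seen, because no source states that folds of different lists share a scale. On log2 folds limma also called 0 genes (smallest adjusted p = 0.2), with 500 at an unadjusted p under 0.05, 382 lower and 118 higher, around a median over all genes of -0.24. In 10 of 10 G2/M genes the mean rank score was lower with sgMETTL1, with a median difference of -0.49. CENPF, a kinetochore protein gene, ranked at the 8.55th and 1.77th percentile with sgNS and the 13.9th and 16.9th with sgMETTL1, where 0 is the strongest. CDK1, the mitotic kinase, ranked at 13.6 and 19.5 against 21.6 and 45.5, BUB1 of the spindle checkpoint at 21.7 and 32.6 against 44.6 and 41.0, and the proliferation marker MKI67 at 79.9 and 75.9 against 90.7 and 97.7. Against the other genes the G2/M list ranked lower by limma's camera (preset correlation 0.01, adjusted p = 0.00663), but not with an estimated correlation, a test with few degrees of freedom (estimate -0.026, unadjusted p = 0.0675, adjusted p = 0.945), nor without replicate 2 of sgNS (adjusted p = 0.0506). No member passed limma's test, over all genes or adjusted over the list alone. By limma's fry, which compares a list with no other genes, no list moved one way (smallest adjusted p = 0.193, G2/M genes). By its mixed test G2/M genes (0.0432), stress granule components (0.0153) and translation factors (0.0109) changed in either direction. Stress granule components and translation factors were also called with the mean of a gene's peaks (0.0139 and 0.0288) and on log2 folds (0.000974 and 0.0466). With the mean of a gene's peaks G2/M genes were not called (0.0623). ATF4 targets (0.0241) and interferon-stimulated genes (0.00323) were called in that setting. On log2 folds G2/M genes (0.0466), ubiquitin ligases (0.0322) and glycolysis (0.0466) were called.

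None of the other 13 lists with at least 3 members in the fit differed by camera. Of the 8 known QKI targets, 5 ranked lower and 3 higher, with a median difference of -0.04 (adjusted p = 0.968), for example CTNNB1 at the percentiles 14.9 and 12.9 with sgNS and 16.3 and 14.3 with sgMETTL1. Of the interferon-stimulated genes, IFIT1, IFIT3 and DDX58 (RIG-I) were all higher, with a median of 0.88 (adjusted p = 0.187). The planned comparison of log2 folds did call this list by camera (median 1.40, adjusted p = 0.0424), along with the G2/M list (10 of 10 lower, median -0.87, adjusted p = 0.0208), so the call of interferon-stimulated genes rests on the folds and was not made on ranks. Both calls on log2 folds were lost with an estimated correlation (adjusted p = 0.932 for both lists, unadjusted 0.109 for interferon-stimulated and 0.149 for G2/M genes). PABPC1, the cytoplasmic poly(A)-binding protein gene, had folds of 1.5 and 1.47 with sgNS against 1.11 and 1.11 with sgMETTL1. The value of 1.11 was the smallest fold in each sgMETTL1 list, so its ranks there were at the floor. Adjusted over the stress granule list alone, it was the 1 gene that passed, with a score difference of -1.02 (SE 0.176, limma's adjusted p over all genes 0.325). Over this list alone 0 genes passed on the planned log2 folds, with the replicate number as a block, or without replicate 1 of sgNS, replicate 2 of sgNS or replicate 1 of sgMETTL1. With the mean of a gene's peaks 2 passed, and without replicate 2 of sgMETTL1 1 passed.

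By gene, limma called 0 of 4150 at an FDR of 5% (smallest adjusted p = 0.221), and 408 had an unadjusted p under 0.05, 196 lower and 212 higher with sgMETTL1. With no difference, 5% of the 4150 would be expected there. Some genes are not separate observations. PCDHA1 to PCDHA6, PCDHA8 to PCDHA11, PCDHA13, PCDHAC1 and PCDHAC2 all had the same folds (44.0 and 44.4 with sgNS, 119 and 88.8 with sgMETTL1). Each was counted among the 212, which raises the number on the higher side. The genes with the smallest p were SENP6, a SUMO protease gene, with a score difference of -2.39 (SE 0.18; folds of 25.5 and 21.1 with sgNS and 2.29 and 2.11 with sgMETTL1), C8orf4, CADPS2 and PHIP on the lower side, and INHBB, PDE4A and SOX6 on the higher side; they were picked after their values were seen. Of the 10 genes with the smallest p, 6 had their higher folds at whole steps in both lists of that guide. Examples are SENP6 (11 and 10 steps), CADPS2 (8 and 8), INHBB (7 and 6) and PDE4A (9 and 10). These differences therefore rest on the same coarse values. Whether the higher and lower folds of a gene came from the same site was not examined. Ranks within a list correlated across genes at 0.877 between the sgNS lists, 0.855 between the sgMETTL1 lists and 0.837 to 0.846 between guides (Spearman, across genes, which are not independent replicates). On simulated data of the same size, 70% of genes changed by a score of -3 were recovered, 36% at -2 and 4% at -1, so a moderate difference was not detectable with 2 lists per guide.

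**Figure D4:**
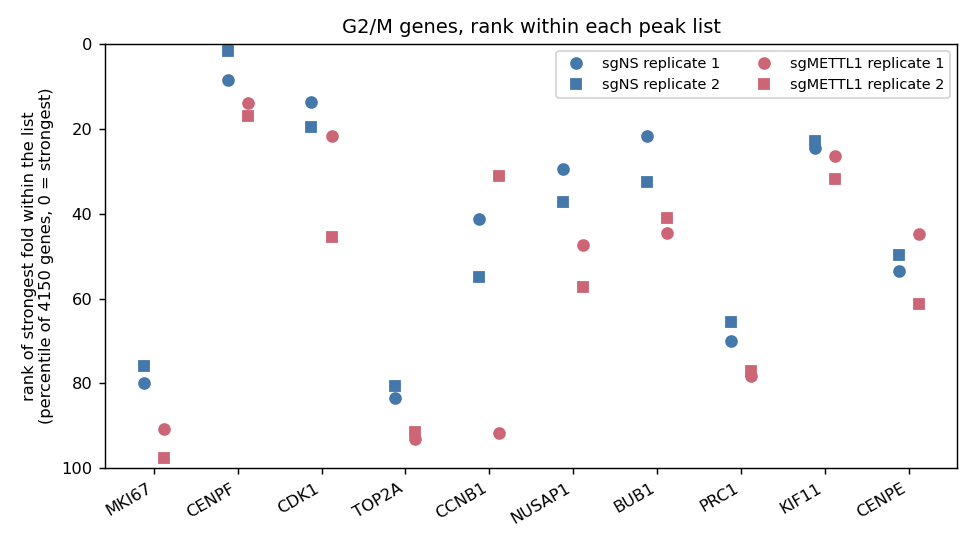
Rank of the strongest peak of 10 G2/M genes within each of the 4 lists, as the percentile among 4150 genes (0 is the strongest, at the top), with sgNS in blue and sgMETTL1 in red. CENPF moves from 8.55 and 1.77 to 13.9 and 16.9, and CCNB1 is spread from 31.1 to 91.8 within sgMETTL1.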

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

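The tests of explanations in this part were chosen after the result was seen. G2/M genes stood out because a test of the difference between guides, camera on ranks within the lists, called them: their median score difference, sgMETTL1 minus sgNS, was -0.494, with 10 of 10 members lower. Genes of a similar rank did not move alike, since 0 of 10000 random lists matched on the mean score had as low a median (percent of lists: 0; 95% of them lay between -0.248 and 0.258). Nor did genes with similar evidence in sgNS move alike, since 0.04% of random lists matched on the mean -log10 p in sgNS had as low a median. The random lists had medians of -0.016 and -0.0615, so matched genes did not fall as a group. They draw on the same scores by which camera had picked the G2/M list, so the rarity of its median is no separate support. These lists treat genes as independent, so a chance difference between samples stays open. With an estimated correlation the adjusted p was 0.945 (unadjusted 0.0675); the estimate was near 0 (-0.026), so the rise came from the few degrees of freedom of that test. A fall in QKI7 binding after METTL1 loss, or a change of the share of dividing cells, may also underlie it; neither was tested, since input levels were not analysed here.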

How the results depend on the processing

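Added after the data were seen were the ranks in place of log2 folds, the rankings by fold, the background of all protein-coding genes and the position within the gene's span. The cause was not tested unless it follows from the setting. Replicate sharing of peaks (81.2% with sgNS and 75.6% with sgMETTL1, mean of both directions) was 66.2 and 59.5% with 50% reciprocal overlap; with equal numbers of peaks by p it was 84.9% with sgNS at 9388 peaks and 90.4 and 86.1% at 4694, and by fold at 4694 it was 75.8 and 72.2%. It was higher with sgNS under each of these. Leaving out a list leaves no replicate pair to share. Lost and gained genes numbered 1075 and 190 by peak overlap in place of the gene name, 200 and 153 at 9388 peaks by p, 127 and 127 at 4694, 205 and 156 by fold at 9388, 178 and 98 at 4694, and 277 and 95 at a fold of at least 2 times the minimum. Without 1 list they ran from 504 (without replicate 1 of sgNS) to 647 (without replicate 2 of sgNS) lost and from 166 (without replicate 2 of sgNS) to 333 (without replicate 2 of sgMETTL1) gained, as fewer lists must agree or object. Gene lists called against all protein-coding genes numbered 11 with sgNS and 10 with sgMETTL1. Against genes of both replicates of either guide 0 were called with sgNS, where even full presence of chromatin regulators could not be called.

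By gene, limma called 0 under all alternatives, with 313 to 500 genes at an unadjusted p under 0.05; a lone list was assumed to vary like the pair. On log2 folds, the planned scale, 68.6% of genes were lower with sgMETTL1, against 52.2% on ranks and 46.9% with lists centred on their median (median over all genes -0.24 before and 0.04 after). Ranking and centring bring that share near 50% by construction, so they do not show where the lower folds came from. Camera called 1 list; it called 2 on log2 folds (also interferon-stimulated genes), 0 with an estimated correlation, and 0 to 1 without 1 list. The adjusted p of G2/M genes was 0.945 with an estimated correlation, 0.00362 to 0.0208 under the other alternatives, and 0.0237 to 0.0506 without 1 list, above the threshold without replicate 2 of sgNS. The replicates share only a number: deviations of same-numbered lists correlated at -0.0015 across genes, and with the replicate block 0 genes were called (380 at an unadjusted p under 0.05) and G2/M genes kept an adjusted p of 0.00878. Not run, since they need read counts or sequence: DESeq2, library size scaling, filters on low counts, the pseudocount, a 2-fold threshold, transcript parts and motif controls. Without read totals, depth limits every statement on absent peaks.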

Other observations

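The tests of explanations in this part were all chosen after the results were seen. IGF2 dominated the evidence of every list. Its peak had a -log10 p of 737000 and 828000 with sgNS and 781000 and 949000 with sgMETTL1, 27.8 and 30.2 times that of the next gene, H1F0, with sgNS and 45.1 and 51.6 times that of the next gene, MBD2, with sgMETTL1.

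Some peaks joined many exons, as along a spliced mRNA and not at a single 3' site. Peaks of at least 10 exon blocks were listed in all 4 lists for AGRN, a basement membrane proteoglycan gene, DVL1 of the Wnt pathway, SSB, which encodes the La protein, and the collagen gene COL27A1. The DVL1 peak of 15 blocks (chromosome 1, 1335278 to 1349112) had the same bounds in every list, with the authors' folds at 46.5 and 45.9 with sgNS and 51.0 and 35.0 with sgMETTL1. COL27A1 was joined over 56 and 55 blocks with sgMETTL1 and over at most 19 in a peak with sgNS. Such a peak of COL7A1 was listed in both sgMETTL1 lists (22 and 16 blocks for the longer) and in neither sgNS list, and those of DVL3, HIPK2, PLEC and DMPK in both sgNS lists and neither sgMETTL1 list. These patterns depend on the bound of 10 blocks and are not a loss of all peaks. The DVL3 peak joined just 10 blocks in both sgNS lists, and DVL3 still had peaks with sgMETTL1, at up to 360-fold and 250-fold. The genes named so far were chosen after their values were seen, by block number and by which lists held such a peak. TTYH3, CDK8 and WAC had one in lists of both guides but not in all 4. AGPAT3, SCRIB, SNX9 and TMEM131 had one in a single sgNS list.

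More genes were lost than gained with sgMETTL1, 302 against 99. Lost over gained genes fell from 3.05 to 1.31 among equal numbers of top-ranked peaks (9388 per list), by p and by fold alike. At 4694 per list it was 1 by p but 1.82 by fold. It stayed at 2.92 with a fold of at least 2 times the minimum, and by peak overlap in place of the gene name 1075 genes were lost and 190 gained. Equal numbers of peaks remove the difference in list length whatever shortened the sgMETTL1 lists, and the 2 rankings gave different ratios at 4694 per list. METTL1 loss having removed QKI7 from some transcripts and the lengths of the lists therefore cannot be told apart. Fewer reads behind the sgMETTL1 peak calls may contribute. At 172 genes whose best peak had folds within 1.2-fold in all 4 lists, the -log10 p with sgMETTL1 was 0.63 of that with sgNS (median), against 0.972 and 1.08 between replicates, which is what fewer reads would give if the folds of the lists share a scale. Of these genes 91.9% had a lower mean -log10 p with sgMETTL1. IGF2, with folds within the same limit, did not. Its -log10 p was 737000 and 828000 with sgNS and 781000 and 949000 with sgMETTL1. The lower values thus did not extend to the strongest peak by p. Read totals, which would settle whether reads were fewer, were not analysed here.

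The QKI peak of 8 exon blocks lost rank with sgMETTL1 and the QKI 3' peak did not. A general loss of reads would move the peak no further in rank than genes of similar rank. The log2 ratio of its mean ranks by p was 1.94. It was compared with 193 genes in the top 200 by p in both sgNS lists and listed in all 4, which leaves out any gene absent from an sgMETTL1 list. Of these 193 genes 1, H1F0, had as large a ratio (2.86). The QKI peak thus fell further than all but 1 of them. The QKI peak ranked 13th and 12th with sgNS, and H1F0 stood next to IGF2 by p in both sgNS lists. Genes near those ranks were not compared alone, and the QKI peak was ranked among peaks but the 193 among genes. The count therefore does not exclude a general loss of reads. The limit used, under 5% of such genes, was set after this count was seen and is the one used for the random lists. Less RNA from the QKI7 transgene in sgMETTL1 cells could lower the peak, if the transgene carries those exons and not the 3' part, which the labels do not say. Less RNA alone would leave the IP over input fold in place if RNA of the transgene and of the cells' own QKI gene were recovered alike, and the peak's move by 17.9 percentile points by fold argues against that form. If both kinds of RNA lie under the peak and differ in recovery, their mixture would move the fold too, and the peak lists do not separate them, so less transgene RNA stays open. A lower recovery of those exons by QKI7 after METTL1 loss was not tested.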
